A study of Mus musculus with 16 samples.

How the data were processed

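Whole ovaries and whole testes of mice were profiled by total RNA sequencing in conventionally raised animals (CV), which carry a normal gut microbiota, and in germ-free animals (GF), which are raised without microbes. The labels give the strain as C57BL/6j, an age of 15 to 16 weeks, collection between zeitgeber times 2 and 4 (hours after lights on) and feeding ad libitum. Each of the 16 libraries was placed in 1 of 4 groups by its labels: 4 CV and 5 GF ovaries from females, and 4 CV and 3 GF testes from males. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. Tissue and sex were one factor, and no label gives a batch, a cage, a litter or an ovarian cycle stage.

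Per the labels' protocols, RNA was extracted with a column kit that keeps small RNA, and libraries were made from 250 ng of total RNA with a stranded total RNA kit after ribosomal RNA depletion and 12 cycles of PCR. Pools of 24 libraries were sequenced on 8 lanes as paired reads of 100 nt. The authors deposited a single table of whole-number read counts per gene, not normalised, with 38087 genes and 16 columns. STAR 2.4.0i and the mm10 build are named in the submitters' processing notes. The counting tool, the annotation and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the histone genes, could therefore be split or shared in ways that the table does not show. All 16 columns matched a sample by name. Totals ran from 12912251 to 15907297 counts in the ovary and from 25880591 to 28266867 in the testis, so a gene of a given level was measured with less counting error in the testis.

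Gene symbols were used as the file gives them. Positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, joined by gene identifier: 36308 genes had a position and 1779 did not. Where the annotation names a gene otherwise, both names are given. None of the 13 protein genes of the mitochondrial genome was in the table, so that list has no result.

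Counts were tested in each tissue by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, edgeR's expression filter and robust dispersion estimates. The tissue by microbiota interaction was tested over all 16 libraries as the GF minus CV difference in the testis less that in the ovary. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes at an adjusted p under 0.05 are said to be called. Log2 fold changes are GF over CV with their standard errors (SE). Levels are CPM, computed from the deposited counts with TMM-normalised library sizes, as mean ± SD. The sex and germ cell genes that check the labels are given as CPM of the raw total instead, which changes their SD slightly. Overlap between tissues was tested by two-sided Fisher's exact tests over genes tested in both.

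Gene lists, 42 in all (28 for both tissues, 7 for the ovary and 7 for the testis), were written from textbook knowledge, and 807 of their 829 symbols were found, 15 of them through the annotation's name. Lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, two-sided, adjusted over the lists of the tissue. Each was tested again with an estimated correlation, and with fry, which asks whether the members move one way without comparing them with other genes. The groups, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the alternatives named below as added.

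The named genes were, per tissue, the 10 most raised and 10 most lowered called genes with a mean of at least 1 CPM in one group and group ranges that did not overlap, up to 4 called members of each list by smallest p, and always 12 genes of the hormone axis and 4 of the clock. Predicted and unnamed genes were counted and not named. For the interaction the 10 of smallest p were named under the same conditions, and for genes called in both tissues the 10 with the largest smaller change. The rule did not state for the last set that predicted, unnamed and repeated RNA family names are passed over, and they were passed over there as well. Some genes that the rule takes are not reported here, though they stay in the fits, the list tests and the counts over genes. Genes named outside the rule were chosen after their values were seen, among them list members given as examples without a call over all genes and, in the testis, Nnt and Wdfy1.

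Replicate pairs were compared by a chi-square test over genes with at least 20 counts in the pair. The statistic per degree of freedom ran from 2.37 to 34.3, so no pair agreed within sampling noise and each library was counted once. The labels number the libraries within groups. In the ovary, libraries of the same number deviated together from their group means in each of 4 pairs (correlation across genes of 0.2 to 0.367), so the numbers were taken to pair the ovaries, and the fit with the replicate number as a block is given beside a result whose call it changes or whose count it moves by over 1.5 times. The pairing comes from this correlation and not from a label, and in 2 of the 4 pairs each library correlated best with its partner. Libraries of different numbers correlated at -0.427 to 0.383. The highest value of all was that of CV2 with GF5, and CV3 correlated more with GF4 (0.238) than with its partner GF3 (0.2). The pairing is therefore uncertain, and so are the results that rest on it.

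The fits were tested on simulated counts with 200 changed genes. In the ovary, over 18100 genes, 4% of genes changed 1.25-fold were called, 54.2% at 1.5-fold, 75% at 2-fold and 96% at 4-fold, with 9.77% false calls. In the testis, over 20255 genes, the shares were 44%, 73.5%, 89.8% and 98%, with 6.94% false calls. For the interaction, over 21981 genes, they were 0%, 10.2%, 44.9% and 70%, with 4.62% false calls. A list raised 1.5-fold was recovered by camera, by camera with an estimated correlation and by fry, with 0 other lists called. The simulated genes varied independently of each other, unlike the real ones (estimated correlation of 0.743 in the ovary cell cycle list). The simulation therefore does not test how often correlated lists are called falsely.

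Alternatives were RLE and upper-quartile scaling, no filter or a stricter filter (1 CPM), DESeq2 1.42.0, limma-voom with and without quality weights, the replicate block, a joint fit of both tissues, a corpus luteum score as a covariate for ovarian cycle stage, and each library left out in turn. The block fits held only libraries with a partner of the same number, and so left out GF5 of the ovary and CV4 of the testis. Added after the data were seen were fits without genes in 5 Mb bins in which calls clustered, a correction for GC content and gene length, fits on the partnered libraries without a block, the block in the ovary alone for genes called in both tissues, and the corpus luteum covariate for the lists. Bins were compared with the rest of the genome by Fisher's exact test for called genes with an absolute log2 fold change of at least 0.5. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and plots.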

Results

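Total RNA was measured in 9 ovary and 7 testis libraries of mice with and without a gut microbiota. The ovary set held 4 conventionally raised (CV) and 5 germ-free (GF) libraries from females, and the testis set 4 CV and 3 GF libraries from males. Total counts per library ran from 12912251 to 15141027 in CV ovaries and from 13294039 to 15907297 in GF ovaries. In the testis they ran from 25880591 to 28266867 in CV and from 26015487 to 27188919 in GF libraries. The design implies 4 questions: what differs in the ovary without microbes, what differs in the testis, whether the 2 tissues differ in their response, and which genes respond in both.

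Genes of known sex and germ cell expression matched the tissue labels. Xist, the RNA that silences an X chromosome in females, stood at 1374 ± 111 CPM in CV and 1293 ± 142 CPM in GF ovaries, and at no more than 5.1 CPM in any testis library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 1 count in any ovary, while Ddx3y averaged 20.3 CPM in CV and 19.3 CPM in GF testes. The sperm protamine gene Prm1 averaged 3003 ± 86.7 CPM in CV and 2867 ± 53.7 CPM in GF testes, and Tnp1, a transition protein of spermatids, 1738 ± 60.1 and 1788 ± 6.52 CPM (SD, n = 4 and 3). In the ovary the oocyte genes Gdf9 (52.2 ± 14.5 CPM in CV, 41.8 ± 9.68 in GF) and Zp3 (25 ± 4.55 and 21.3 ± 4.34) varied more between libraries. The biological coefficient of variation was 18.5% in the ovary and 4.17% in the testis, so smaller changes could be called in the testis. Its first principal component (33.6% of variance) separated CV from GF testes, and that of the ovary (30.6%) did not separate the groups, nor did the second (18.1%). The third (14.3%) did (4.98 to 23.1 in CV, -38.7 to 2.14 in GF libraries).

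In the GF ovary the RNA of Nnt, the mitochondrial transhydrogenase that makes NADPH, rose from 74.3 ± 2.62 to 159 ± 19.8 CPM (SD, n = 4 and 5). Wdfy1, a FYVE-domain protein of endosomes, rose from 31.9 ± 2.92 to 72.4 ± 6.12 CPM. Igha, the constant region of the immunoglobulin A heavy chain, fell from 9.88 ± 1.17 to 0.354 ± 0.255 CPM, resting on 562 counts in the 4 CV and 25 in the 5 GF libraries. Ero1lb, an oxidase of disulphide bond formation in the endoplasmic reticulum, fell from 39.5 ± 3.61 to 21.3 ± 1.99 CPM, and Ggps1, which makes the isoprenoid geranylgeranyl diphosphate, from 63.3 ± 2.42 to 41.2 ± 3.98 CPM. Several histone genes of chromosome 13 moved in both directions: Hist1h4i rose from 7.92 ± 1.68 to 30.1 ± 4.55 CPM and Hist1h4m fell from 11.9 ± 1.19 to 2.62 ± 0.547 CPM. In log2 terms (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), Nnt changed by 1.09 (SE 0.087, adjusted p = 0.000391), Wdfy1 by 1.18 (SE 0.0844, adjusted p = 0.000391) and Igha by -4.79 (SE 0.35, adjusted p = 0.000391). Ero1lb changed by -0.89 (SE 0.0887, adjusted p = 0.00166), Ggps1 by -0.62 (SE 0.0759, adjusted p = 0.00506), Hist1h4i by 1.93 (SE 0.165, adjusted p = 0.000556) and Hist1h4m by -2.18 (SE 0.17, adjusted p = 0.000391). In GRCm38, Nnt (ENSMUSG00000025453) lies on chromosome 13 at 119335448 to 119408997 and Wdfy1 (ENSMUSG00000073643) on chromosome 1 at 79702262 to 79776143. Igha (AC160982.1 in the file, ENSMUSG00000095079) lies on chromosome 12 at 113254830 to 113260236. Ero1lb (ENSMUSG00000057069, 12565874 to 12611396), Ggps1 (ENSMUSG00000021302, 14050659 to 14063488), Hist1h4i (ENSMUSG00000060639, 22040636 to 22041362) and Hist1h4m (ENSMUSG00000069306, 21811746 to 21812147) all lie on chromosome 13. The labels do not give the colonies of origin. A strain background that differs between CV and GF colonies may account for part of these differences and of those in the testis, as set out below for clustered calls.

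Of 18095 genes tested in the ovary, 32 were called, 20 higher and 12 lower in GF, and 1172 had an unadjusted p under 0.05. The median absolute log2 fold change of the 32 was 1.95, and 28 exceeded 1. Their CV and GF ranges did not overlap in any of the 32 cases. Over all genes tested 2.73% had groups that did not overlap, against 1.59% given by chance. Predicted or unnamed genes made up 13 of the 32. Chromosome 13 held 20 of the calls, 2.93% of its tested genes against 0.0528% elsewhere (Fisher's exact test, adjusted p = 5.92e-21). Of the 32 calls, 19 lay in 5 Mb bins where calls clustered in either tissue, which held 1.45% of the tested genes. The bins were chosen for holding such calls, so these shares do not test the clustering. Of the named genes, Nnt, Igha, Dynlt1b, Efcab7, SLC25A37, Cntnap5a and ERDR1 lay outside those bins. Wdfy1, Ero1lb, Ggps1, Gpr137b, Prl2c5 and the named histone genes other than Hist1h2bm lay in them. Hist1h2bm had no position and could not be placed in or out of a bin. Without genes in the bins 10 of the 13 other calls, 3 of which had no position, were left, and none was added. Dynlt1b (adjusted p = 0.0782), Cntnap5a (0.0657) and AC183097.2 (0.0712), the last chosen after its values were seen, were then not called. With replicate number as a block, and so without GF5, 91 genes were called (34 higher, 57 lower). DESeq2 called 95 and the joint fit of both tissues 93. Each of these 3 sets held all of the 32.

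Further rises in the GF ovary were Gpr137b, a lysosomal membrane protein (10.7 ± 1.57 to 22.5 ± 1.88 CPM, log2 1.08, adjusted p = 0.00252), Efcab7, a cilium protein (5.4 ± 0.504 to 10.4 ± 0.529 CPM, log2 0.95, adjusted p = 0.0036), and the histone genes Hist1h2ao (log2 4.10, adjusted p = 0.000674), Hist1h2bp (2.10, 0.00205) and Hist1h4n (1.26, 0.00391). Prl2c5, a member of the placental prolactin family, rose by 4.35 (SE 0.583, adjusted p = 0.0107). It had 3 counts in the CV and 90 in the GF libraries, a ratio of 23.6 with a 95% counting interval of 7.83 to 117. Its counts equalled those of an annotated 7SK RNA copy at 12666051 to 12666314 of the same chromosome in 5 of 9 ovary and 7 of 7 testis libraries, so its reads could not be assigned to it alone. Dynlt1b, a dynein light chain, rose by 1.09 (adjusted p = 0.0323), and its counts lay close to those of AC183097.2, which overlaps it (839 and 848 over the ovary libraries). Further named falls were those of the file's SLC25A37 (Gm16867 in the annotation; -4.96, adjusted p = 0.00295), with 88 and 3 counts, a ratio of 37.3 (95% counting interval 12.3 to 184), ERDR1 (Gm47283 in the annotation; -1.47, 0.00252), Hist1h2bn (-1.45, 0.0211), Hist1h2bm (-1.35, 0.00355) and Cntnap5a, a neuronal adhesion protein (-2.53, 0.0256). The intervals cover counting error only. Histone genes are near-identical copies, and their single values are uncertain. Leaving out 1 library kept 15 of the 19 named calls. Prl2c5 was not called without CV3 (adjusted p = 0.0638; over all settings 0.000329 to 0.0638). Dynlt1b was not called without CV1 (0.119), CV2 (0.109), CV3 (0.171), CV4 (0.104), GF2 (0.0758), GF3 (0.0615) or GF4 (0.0545; over all settings 1.36e-05 to 0.171). It was also not called by limma-voom (0.0586) or without genes in the clustered bins (0.0782). Cntnap5a was not called without CV1 (0.0812), CV3 (0.112), CV4 (0.0824), GF1 (0.0762), GF2 (0.0639) or GF3 (0.0688; over all settings 2.02e-06 to 0.115). Its call also ended with the corpus luteum score as a covariate (0.115) and without genes in the clustered bins (0.0657). Hist1h2bn was not called without CV1 (0.0741), CV3 (0.106), CV4 (0.0993), GF2 (0.05) or GF5 (0.0831; over all settings 9.04e-10 to 0.106). Nor was it called with no filter on low counts (0.0766), with the corpus luteum covariate (0.0781), on the partnered libraries (0.0831) or with the replicate block and the GC and length correction together (0.0589).

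**Figure D1:**
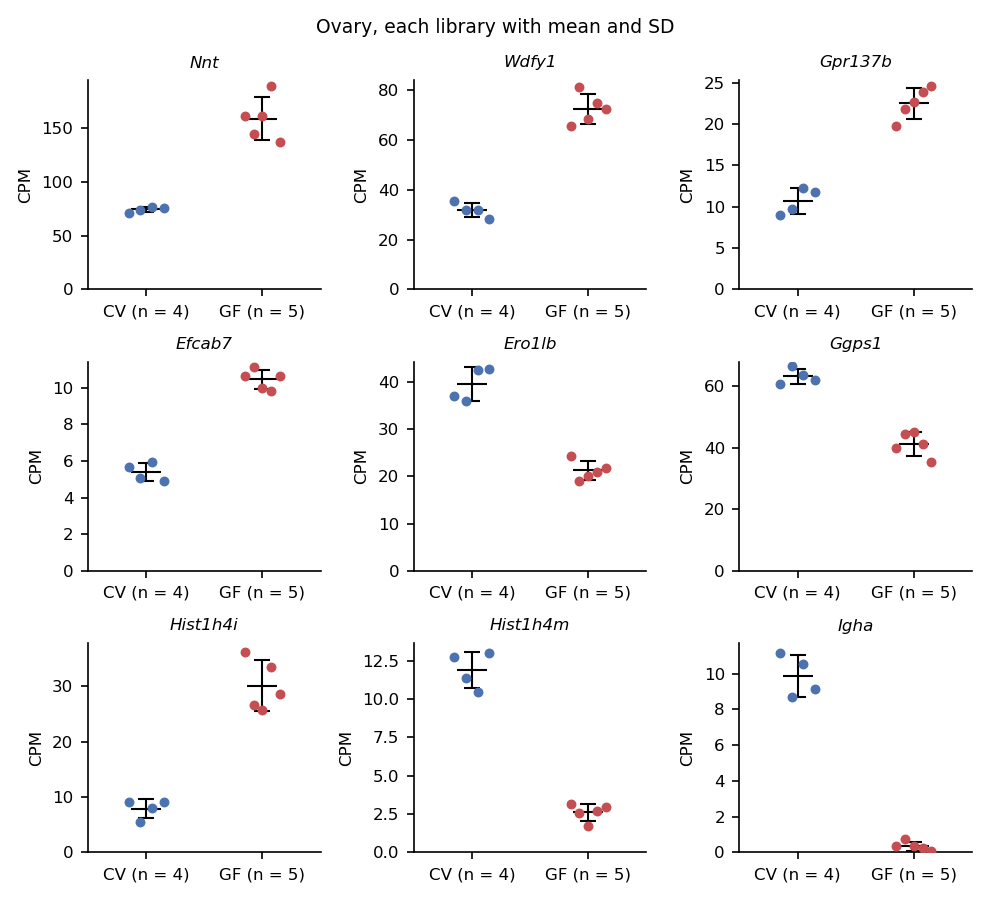
Levels in CPM of 9 genes called in the ovary, each point 1 library (4 CV, 5 GF), with the group mean and SD as bars and the axis starting at 0. The GF points of Nnt, Wdfy1, Gpr137b, Efcab7 and Hist1h4i lie above all CV points, and those of Ero1lb, Ggps1, Hist1h4m and Igha below them.

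**Figure D2:**
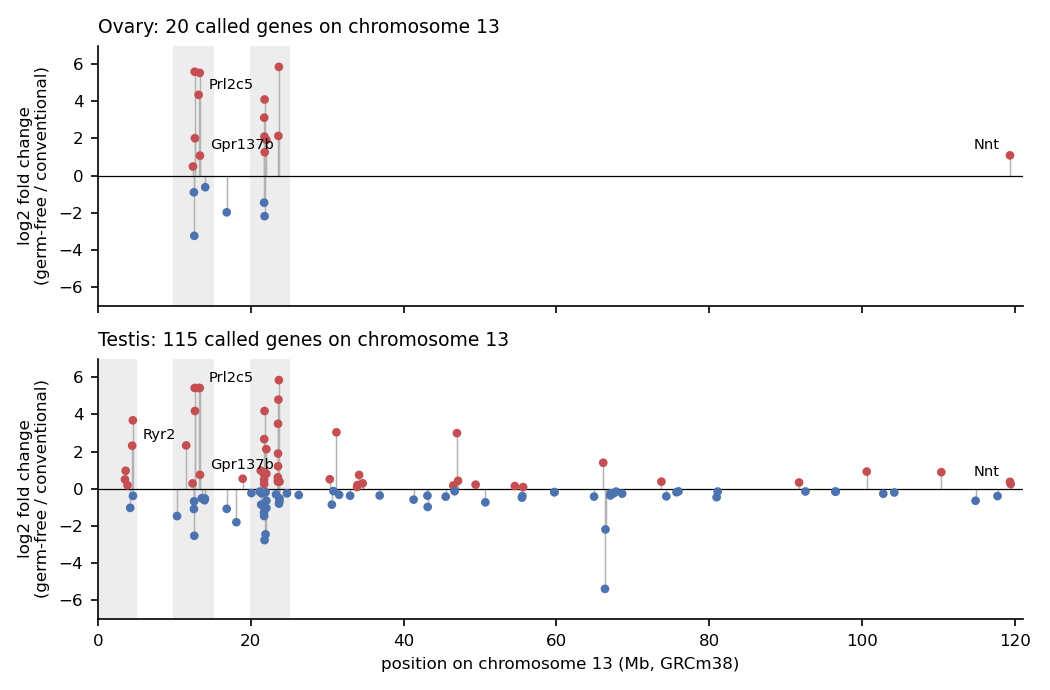
Called genes along chromosome 13 (GRCm38, in Mb) with their log2 fold change, GF over CV, in the ovary (20 genes) and the testis (115 genes), 1 point per gene (red higher, blue lower in GF). Grey bands mark the 5 Mb bins in which calls clustered in that tissue, and Nnt lies outside them near the end of the chromosome.

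With camera's preset correlation the cell cycle, interferon and endothelial lists were called higher in the GF ovary, and the immunoglobulin and B cell list lower. With an estimated correlation the adjusted p was 0.644 for each of the 3 raised lists and 0.604 for the immunoglobulin list, and 0 of 33 lists were called (1 at an unadjusted p under 0.05), as by fry (0, with 1 unadjusted). Of 100 splits of the ovary libraries 41 gave as many lists as the 11 called. Of 24 cell cycle genes 23 had a positive log2 fold change (median 0.17, camera adjusted p = 2.29e-05), among them the replication factors Mcm5 (30.9 to 39.7 CPM, log2 0.36, gene adjusted p = 0.469) and Mcm7 (64.5 to 78.5 CPM, 0.28) and the DNA clamp Pcna (0.17). Of 31 interferon-stimulated genes 26 were positive (median 0.21, adjusted p = 3.73e-05), among them the GTPase genes Irgm2 (48.4 to 66.3 CPM, 0.46) and Igtp (0.45). Of 15 endothelial genes 13 were positive (median 0.16, adjusted p = 8.22e-05), such as the VEGF receptor gene Kdr (92 to 104 CPM, 0.18) and Egfl7 (0.21). In these 3 lists no member was called singly by edgeR, over all genes or adjusted over the list alone, and 5, 8 and 3 members had an unadjusted p under 0.05. Of 13 immunoglobulin and B cell genes 10 were negative (median -0.30, adjusted p = 0.000262). Igha was its 1 member called over all genes. Adjusted over the list alone 3 members were lower: Igha, Igj, the joining chain of polymeric antibodies (Jchain; 4.46 to 1.62 CPM, -1.45), and Ighg2b (-1.37). Igkc, the kappa light chain, stood at -1.32 and Ighm, the heavy chain of immunoglobulin M, at -0.16. Over libraries left out the adjusted p stayed within 2.43e-10 to 0.00296 for the cell cycle, 6.67e-10 to 0.00798 for interferon, 6.67e-07 to 0.00681 for endothelial and 4.66e-05 to 0.00384 for immunoglobulin genes.

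Another 7 lists were called lower in the GF ovary by camera with the preset correlation, with no member called singly by edgeR, over all genes or adjusted over the list alone (6 members at an unadjusted p under 0.05). With an estimated correlation the adjusted p was 0.644 for smooth muscle, oviduct, circadian clock and xenobiotic response genes, 0.730 for adipocyte genes and 0.791 for oocyte and macrophage genes. Smooth muscle and myoid genes were negative in 10 of 11 (median -0.22, adjusted p = 0.0189), such as the actin gene Acta2 (-0.19) and Mylk (-0.22), and the call ended without CV2 (0.139), GF1 (0.103) or GF4 (0.0757; range over libraries left out 3.17e-05 to 0.139). Oviduct genes were negative in 13 of 16 (median -0.18, adjusted p = 0.0206), such as the epithelial gene Epcam (-0.46) and Pax8 (-0.37), a transcription factor of the female tract, and not called with the corpus luteum score as a covariate (0.0611) or without CV1 (0.106), GF3 (0.0625) or GF5 (0.0901; range 0.00384 to 0.106). Circadian clock genes were negative in 16 of 24 (median -0.08, adjusted p = 0.0277), such as Hlf (-0.37) and Per3 (-0.28), and not called with the replicate block (adjusted p = 0.262), with the corpus luteum covariate (0.205) or without CV1 (0.164), CV2 (0.0575) or GF5 (0.13; range 0.00583 to 0.164). Aryl hydrocarbon and xenobiotic response genes were negative in 12 of 18 (median -0.15, adjusted p = 0.029), such as Tiparp (-0.31) and the glutathione transferase Gsta2 (-0.53), and not called without genes in the clustered bins (0.0533) or without CV3 (0.0638), CV4 (0.173), GF1 (0.0522) or GF2 (0.106; range 0.00385 to 0.173). Adipocyte genes were negative in 12 of 15 (median -0.24, adjusted p = 0.029), such as Cidea (-0.63), and not called without CV2 (0.371), CV3 (0.0623), GF1 (0.125), GF2 (0.0513) or GF4 (0.555; range 0.000334 to 0.555). Oocyte genes were negative in 21 of 23 (median -0.19, adjusted p = 0.0336), such as the egg coat gene Zp2 (-0.29) and the growth factor Bmp15 (-0.33), and not called without CV1 (0.511), CV3 (0.162), CV4 (0.303), GF1 (0.0522), GF2 (0.314) or GF3 (0.0625; range 3.74e-13 to 0.511). Macrophage genes were negative in 16 of 19 (median -0.11, adjusted p = 0.0384), such as the lysozyme Lyz2 (-0.21), and not called with the corpus luteum covariate (0.0797) or without CV2 (0.567), CV3 (0.0638), GF1 (0.147) or GF4 (0.837; range 6.98e-05 to 0.837). Without GF1, 7 lists were called in place of 11. With the replicate block and the preset correlation 15 lists were called, among them steroidogenesis (adjusted p = 0.0126), cholesterol biosynthesis (0.00367), innate sensing (0.0192), extracellular matrix (7.83e-06) and ovarian surface epithelium (0.00367). With an estimated correlation and no block the adjusted p of these 5 lists was 0.644, 0.877, 0.791, 0.809 and 0.694.

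Genes of hormone synthesis and hormone response were not called in the GF ovary. Star, which brings cholesterol to the steroidogenic enzymes, stood at 262 ± 134 CPM in CV and 286 ± 129 in GF (SD, n = 4 and 5; log2 0.13, adjusted p = 0.973). Cyp17a1, the androgen-forming lyase, stood at 337 ± 72.6 CPM in CV and 426 ± 450 in GF, where libraries ran from 16.1 to 1182 CPM. Its log2 value of 0.34 ran from -0.63 to 0.65 over all settings, and that of Star from -0.14 to 0.55. Insl3, a peptide of theca cells, stood at 4.13 and 7.16 CPM (0.79, adjusted p = 0.75). The steroid enzyme genes Cyp11a1 (0.16), Hsd3b1 (0.20), Hsd3b6 (0.40) and Cyp19a1 (-0.46), the gonadotropin receptors Lhcgr (-0.44) and Fshr (-0.26), and anti-Müllerian hormone Amh (0.04) had adjusted p up to 0.987. The clock genes Arntl (0.22), Per1 (-0.20), Dbp (-0.12) and Nr1d1 (-0.04) were not called. As lists, steroidogenesis (21 genes, median 0.14, camera adjusted p = 0.253), hormone receptors (11, -0.08, 0.466), the growth hormone and IGF axis (18, -0.04, 0.737), cholesterol biosynthesis (24, 0.08, 0.44), cholesterol uptake and transport (20, -0.03, 0.826) and fatty acid metabolism (23, 0.00, 0.676) were not called. Granulosa (20, -0.07, 0.125), theca (15, 0.05, 0.33), corpus luteum (18, 0.08, 0.269), ovulatory response (17, -0.09, 0.158) and ovarian surface epithelium genes (12, -0.19, 0.056) were not called either. With the replicate block steroidogenesis (adjusted p = 0.0126), cholesterol biosynthesis (0.00367) and surface epithelium (0.00367) were called. Surface epithelium was also called with the GC and length correction (0.0298). Granulosa genes were called with the corpus luteum covariate (0.00246). These calls rest on camera's preset correlation. In the fit of all libraries the adjusted p with an estimated correlation was 0.644 for steroidogenesis, 0.877 for cholesterol biosynthesis, 0.694 for surface epithelium and 0.791 for granulosa genes.

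Among the other uncalled lists of the ovary, T and NK lymphocyte genes had a median of 0.36 (12 genes, adjusted p = 0.0791), MHC class II genes 0.05 (10, 0.676), innate sensing genes -0.16 (21, 0.262; 0.0192 with the replicate block) and extracellular matrix genes -0.09 (29, 0.134; 7.83e-06 with the block, 0.0407 with the GC and length correction). The adjusted p with an estimated correlation was 0.791 for innate sensing and 0.809 for extracellular matrix genes. Values for oxidative stress (23 genes, -0.02, 0.466), immediate early (20, 0.01, 0.665), heat shock (15, 0.07, 0.243), retinoic acid (20, 0.02, 0.534) and erythroid genes (9, -0.23, 0.917) likewise missed the threshold. Tight and gap junction genes (20, -0.01, 0.205) had 3 members lower adjusted over the list alone: the junction proteins Cxadr (68.7 to 48.5 CPM, -0.50), Cgn (-0.26) and Cldn11 (-0.76). Replication-dependent histone genes (22, 0.10, 0.659) had 1 member called over all genes (Hist1h4i), and 3 higher and 4 lower adjusted over the list alone. The neutrophil list had too few tested members for the test (4 genes, median -0.34). Median, mean and test differed in sign for 4 uncalled lists: growth hormone and IGF, cholesterol uptake, immediate early and corpus luteum. In all, 2 of 592 list members were called in the ovary, 1 higher and 1 lower, and 53 had an unadjusted p under 0.05. With the preset correlation some of these lists were called without single libraries. T and NK genes were called without CV1 (0.0336), CV2 (0.0204), CV3 (0.0265) or GF4 (0.0421; adjusted p = 0.644 with an estimated correlation and all libraries). Extracellular matrix genes were called without CV3 (0.00914), GF2 (0.0119) or GF5 (0.00234; 0.809 with an estimated correlation). Surface epithelium was called without CV1 (0.00494), CV4 (0.0348) or GF2 (0.0102), and granulosa without CV2 (0.0204) or GF4 (8.35e-05). For these 2 lists the adjusted p with an estimated correlation was 0.694 and 0.791. Corpus luteum genes were called without GF1 (0.00778) and steroidogenesis without GF5 (0.0499), against an adjusted p of 0.791 and 0.644 with an estimated correlation.

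In the GF testis the RNA of Ero1lb fell from 268 ± 6.61 to 127 ± 3.37 CPM (SD, n = 4 and 3), and that of Tomm20l, a testis relative of a mitochondrial import receptor, from 38.1 ± 1.94 to 12.9 ± 1.03 CPM. Ryr2, a calcium release channel of the endoplasmic reticulum, rose from 1.19 ± 0.204 to 6.05 ± 0.681 CPM, and Hist1h4i from 5.99 ± 0.237 to 26.3 ± 0.385 CPM. Faim3 (Fcmr in the annotation), the Fc receptor for immunoglobulin M, fell from 3.54 ± 0.478 to 0.384 ± 0.204 CPM. Of genes chosen after their values were seen, Nnt rose from 77.6 ± 2.21 to 101 ± 3.11 CPM and Wdfy1 from 93.5 ± 3.43 to 157 ± 5.69 CPM. In log2 terms (edgeR, Benjamini-Hochberg adjusted), Ero1lb changed by -1.08 (SE 0.0318, adjusted p = 1.78e-25), Tomm20l by -1.56 (SE 0.064, 9.99e-21), Ryr2 by 2.34 (SE 0.156, 1.62e-14), Hist1h4i by 2.14 (SE 0.0711, 9.84e-24) and Faim3 by -3.18 (SE 0.248, 2.01e-12). Nnt changed by 0.38 (SE 0.0363, adjusted p = 4.32e-10) and Wdfy1 by 0.75 (SE 0.035, 6.7e-19). In GRCm38, Ryr2 (ENSMUSG00000021313) lies on chromosome 13 at 11553102 to 12106945, Tomm20l (ENSMUSG00000021078) on chromosome 12 at 71111428 to 71123221 and Faim3 (ENSMUSG00000042474) on chromosome 1 at 130865669 to 130880791.

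Other large rises in the testis were Prl2c5 (log2 5.43, adjusted p = 6.09e-16), Akr1c21, a hydroxysteroid dehydrogenase (0.187 to 2.46 CPM, 3.69, 1.99e-12), the potassium channel Kcnh5 (0.241 to 2.3 CPM, 3.22, 1.16e-10), Tmem37 (2.66 ± 0.574 to 8.74 ± 0.667 CPM, 1.71, 5.41e-13), the lipase Lipi (0.788 to 2.57 CPM, 1.70, 6.56e-05), and the histone genes Hist1h2ao (4.19), Hist1h2ae (3.50) and Hist1h2bf (1.90). Other large falls were SLC25A37 (log2 -5.77, 1.61e-13, and -9.32 to -5.24 over all settings), with 321 and 4 counts, a ratio of 59.8 (95% counting interval 23.1 to 221), the neuromedin receptor Nmur1 (3.5 to 0.643 CPM, -2.45, 6.14e-11), the cadherin Cdh20 (1.22 to 0.399 CPM, -1.60, 0.000222), the vitamin E binding protein Afm (3.78 to 1.26 CPM, -1.58, 4.91e-08) and the histone genes Hist1h4m (-2.75), Hist1h2bm (-1.60) and Hist1h2bn (-1.46). Cdh20 was not called in the joint fit of both tissues (adjusted p = 0.245; over all settings 1.95e-05 to 0.245). Of 64 histone genes tested in the testis 15 were higher and 10 lower. Of 20269 genes tested, 1638 were called, 744 higher and 894 lower in GF, and 3939 had an unadjusted p under 0.05. The median absolute log2 fold change of the called genes was 0.22, with 114 above 1 and 1357 below 0.5, and 410 were predicted or unnamed. The groups of 1504 of them did not overlap, and 17.1% of all genes had groups that did not overlap, against 5.71% by chance. Chromosome 13 held 115 calls (15.5% of its genes against 7.88% elsewhere, Fisher's exact test, adjusted p = 3.75e-10), chromosome 1 143 (12.9%, 3.9e-07) and chromosome 12 77 (11.4%, 0.0178). Bins of 5 Mb with clustered calls numbered 8 of 549, and 111 of the 1638 calls lay in them. Of the genes named above for the testis, Ero1lb, Tomm20l, Ryr2, Wdfy1, Prl2c5, Akr1c21, Kcnh5, Tmem37, Nmur1 and the histone genes other than Hist1h2bm lay in these bins. Hist1h2bm had no position and could not be placed. The joint fit of both tissues called 122 genes, each among the 1638, and without GF2 996 were called, 964 of them among the 1638.

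With camera's preset correlation both spermatid lists were called lower in the GF testis. With an estimated correlation the adjusted p was 0.755 for both, and 0 of 33 lists were called (1 at an unadjusted p under 0.05), as by fry (0, with 5 unadjusted). Of 19 round spermatid genes 17 had a negative log2 fold change (median -0.09, camera adjusted p = 5.41e-05) and 7 fell singly, with 8 lower and 1 higher adjusted over the list alone. Of 18 elongating spermatid genes 16 were negative (median -0.07, adjusted p = 2.70e-05) and 4 fell singly, with 7 lower adjusted over the list alone. Catsper4, a calcium channel subunit of the sperm tail, fell from 99.6 ± 3.31 to 84.4 ± 1.24 CPM (SD, n = 4 and 3; log2 -0.24, edgeR adjusted p = 8.92e-06). Izumo1, the sperm protein of gamete fusion, fell from 85.5 to 74.2 CPM (-0.20, 0.000479), the acrosomal gene Acrv1 from 193 to 173 CPM (-0.16, 0.00125), and Odf1, of the outer dense fibres of the tail, from 1220 ± 39.5 to 1099 ± 21.3 CPM (-0.15, 0.000131). Over libraries left out the adjusted p of the lists stayed within 4.5e-09 to 0.00129 and 2.76e-10 to 0.00671. Spermatogonia genes had a positive median (18 genes, 0.15, adjusted p = 0.146) with 1 member higher over all genes and 1 adjusted over the list alone. Meiotic spermatocyte genes (24 genes, 0.03, adjusted p = 0.326) had 3 higher and 2 lower over all genes, and 4 higher and 2 lower adjusted over the list alone. Piwil1, which binds piRNAs in spermatocytes and spermatids, rose from 351 ± 18.2 to 420 ± 2.49 CPM (0.26, 3.07e-07). Sertoli (22 genes, -0.04, 0.769), Leydig (16, -0.00, 0.877) and epididymis genes (5, -0.01, 0.827) had no member called, over all genes or adjusted over the list alone (1, 1 and 0 members had an unadjusted p under 0.05).

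**Figure D3:**
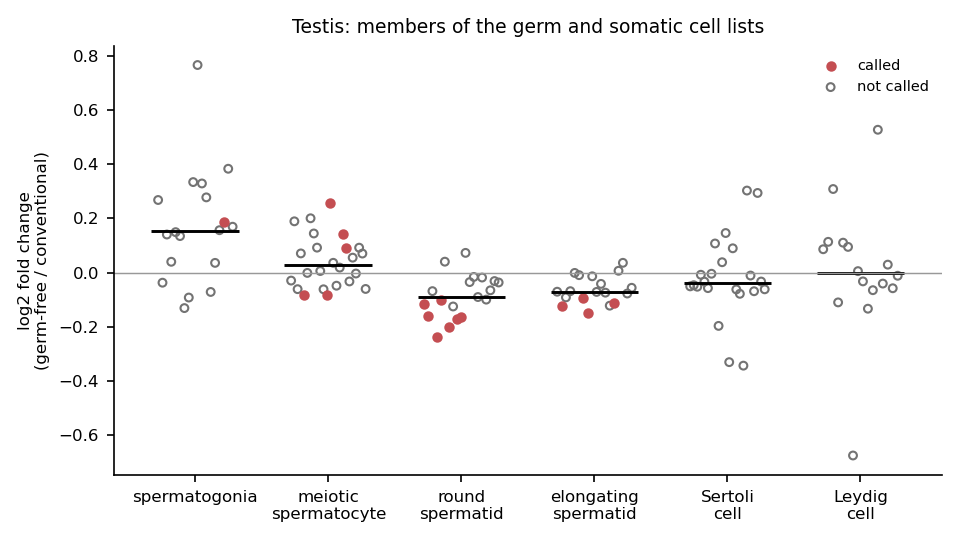
Log2 fold change (GF over CV, 3 against 4 libraries) of each member of 6 cell type lists in the testis, 1 point per gene, filled where called, with the list median as a bar. Medians lie at 0.15 for spermatogonia, -0.09 for round and -0.07 for elongating spermatid genes.

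Genes of lipid handling, immunity and growth changed singly in the GF testis while their lists were not called. Apoe, the lipoprotein carrier of cholesterol, rose from 64.6 ± 2.87 to 76.4 ± 2.34 CPM (SD, n = 4 and 3; log2 0.24, edgeR adjusted p = 5.16e-05), the oxysterol-binding Osbpl1a from 114 to 135 CPM (0.24, 1.68e-06) and the fatty acid transporter Cd36 from 29.9 to 35.1 CPM (0.23, 0.00453; in a clustered bin of chromosome 5), while the lipid droplet coat gene Plin2 fell from 49.3 to 42.4 CPM (-0.22, 0.00276). Acly, which makes cytosolic acetyl-CoA, rose by 0.18 (0.00302) and Igfbp2, a binding protein of IGF, by 0.41 (0.00332). Lcn2, an iron-scavenging acute phase protein, fell from 124 ± 6.57 to 98 ± 3.57 CPM (-0.34, 4.91e-08), and the T cell receptor subunit Cd247 fell by 0.37 (0.00141). The transcription factor Klf4 fell from 183 ± 4.57 to 157 ± 1.39 CPM (-0.22, 2.54e-06), the replication helicase subunit Mcm6 rose from 27.1 to 37.9 CPM (0.48, 9.89e-08) and the matrix proteoglycan Dcn fell from 39.8 to 28.3 CPM (-0.49, 6.49e-06). The junction gene Marveld2 rose by 0.93 (0.00301). Of endothelial genes Vwf, the blood clotting factor, rose by 0.47 (0.00383) and Egfl7 by 0.43 (0.00433). The histone genes Hist1h4c and Hist1h2bj, also in clustered bins, fell by 0.79 (3.94e-19) and 1.03 (7.95e-09). The calls of this paragraph held without each library in turn. All but those of Hist1h4c and Hist1h2bj ended in the joint fit of both tissues, as did those of Catsper4, Izumo1, Acrv1, Odf1 and Piwil1.

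Another 19 list genes were called in the testis with all libraries but not without at least 1 of them (adjusted p without that library in brackets), and each of them was lost in the joint fit. The isoprenoid synthase Fdps was higher by 0.14 (edgeR adjusted p = 0.0333; CV1 0.0555, CV3 0.108, CV4 0.0775, GF1 0.143, GF2 0.256). Of immune genes, Lyz2 was lower, at -0.22 (0.0493; CV1 0.0938, CV2 0.0511, CV3 0.0917, CV4 0.0764, GF1 0.0542, GF2 0.184, GF3 0.152), and the cytokine gene Il1b higher by 1.08 (0.0195; CV1 0.0513, CV4 0.0555, GF2 0.214, GF3 0.0517). Of stress and early response genes, the antioxidant enzyme Srxn1 stood at -0.18 (0.0414; CV2 0.125, CV3 0.148, GF1 0.061, GF2 0.261), Jund at -0.15 (0.0293; CV2 0.114, CV3 0.0824, GF1 0.0859, GF2 0.0785, GF3 0.123) and the cochaperone Bag3 at -0.18 (0.0256; CV3 0.0602, GF1 0.155, GF3 0.0547). The proliferation marker Mki67 stood at 0.11 (0.0441; CV1 0.0795, CV2 0.132, CV3 0.127, GF1 0.161, GF2 0.185, GF3 0.0851) and the retinol dehydrogenase Rdh10 at 0.22 (0.015; GF2 0.103, GF3 0.112). Of matrix and muscle genes, Timp2 stood at -0.08 (0.0399; CV1 0.0608, CV2 0.121, CV3 0.101, GF2 0.102, GF3 0.178), Actg2 at -0.14 (0.00561; GF2 0.0632, GF3 0.0824) and Acta2 at -0.16 (0.0393; CV1 0.115, CV4 0.0894, GF1 0.0835, GF2 0.212, GF3 0.0592). Of germ cell genes, Uchl1 of spermatogonia stood at 0.19 (0.0172; CV3 0.0511, GF2 0.174), the meiotic genes Stag3 at 0.09 (0.0174; CV2 0.0511, CV3 0.074, GF1 0.091, GF2 0.0611, GF3 0.089), Spo11 at 0.14 (0.0184; CV3 0.0739, GF1 0.0574, GF2 0.207) and Hspa2 at -0.08 (0.0296; CV1 0.0724, GF2 0.17, GF3 0.109), and the spermatid genes Spaca1 at -0.17 (0.0128; GF1 0.0578), Spata18 at -0.11 (0.006; GF2 0.111), Cabyr at -0.12 (0.00747; GF2 0.0613) and Oaz3 at -0.09 (0.0181; CV2 0.0539, CV3 0.0874, GF2 0.116, GF3 0.121). DESeq2 ended the calls of Fdps (0.0756), Lyz2 (0.116), Srxn1 (0.0737), Mki67 (0.0825) and Acta2 (0.0679), and limma with quality weights those of Fdps (0.0661), Mki67 (0.0509) and Acta2 (0.0645). Lyz2 and Mki67 were not called by limma-voom (0.0565 and 0.0601) or with no filter (0.0627 and 0.0877). The GC and length correction ended the calls of Lyz2 (0.0728), Mki67 (0.0578) and Oaz3 (0.0697). Mki67 was also lost with both other scalings (0.0514 and 0.0598) and without genes in the clustered bins (0.0564). Over all settings the adjusted p of these 19 ran up to between 0.403 (Il1b) and 1.

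Hormone and clock genes were not called in the GF testis. Star stood at 88.2 CPM in CV and 87.2 in GF (log2 -0.01, edgeR adjusted p = 0.989), Cyp17a1 at 215 and 266 CPM (0.31, 0.661), and Insl3, the peptide hormone of Leydig cells, at 450 and 430 CPM (-0.07, 0.258). Lhcgr, the luteinising hormone receptor, stood at 5.08 and 7.29 CPM (0.53, 0.239). Values for Cyp11a1 (0.11), Hsd3b1 (-0.03), Hsd3b6 (-0.13), Hsd17b3 (0.01), Cyp19a1 (0.16), Fshr (-0.20) and Amh (-0.24), and for the clock genes Arntl (-0.09), Per1 (-0.04), Dbp (0.08) and Nr1d1 (-0.17), missed the threshold. Lhcgr was called without CV1 (adjusted p = 0.000586) and with no filter on low counts (0.000188; over all settings 0.000188 to 1), and Insl3 without CV3 (0.0363; over all settings 0.0363 to 1).

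The remaining 26 testis lists of hormones, metabolism, immunity, stress and cell types were not called by camera. Those with no member called over all genes were steroidogenesis (21 genes, adjusted p = 0.769), hormone receptors (9, 0.926), circadian clock (23, 0.962), immunoglobulin and B cell (7, 0.376; 2 higher adjusted over the list alone), MHC class II (6, median -0.26, 0.158), interferon-stimulated (25, 0.932), xenobiotic response (17, 0.376), adipocyte (15, median 0.23, 0.483) and erythroid genes (7, 0.796). Members were called in the others. Higher and lower counts were 1 and 0 of 18 for the growth hormone and IGF axis (adjusted over the list alone 1 and 0; list adjusted p = 0.796), 1 and 0 of 23 for cholesterol biosynthesis (0 and 0; median 0.12, 0.0617), 3 and 1 of 19 for cholesterol uptake (3 and 1; 0.223), 2 and 0 of 23 for fatty acid metabolism (3 and 0; 0.237) and 1 and 0 of 20 for retinoic acid genes (1 and 0; 0.237). They were 0 and 1 of 10 for T and NK lymphocyte (0 and 1; 0.63), 0 and 1 of 18 for macrophage (0 and 0; median -0.17, 0.0503), 1 and 1 of 16 for innate sensing (1 and 1; 0.769), 0 and 1 of 22 for oxidative stress (0 and 0; 0.769), 0 and 2 of 19 for immediate early (0 and 2; 0.363) and 0 and 1 of 15 for heat shock genes (0 and 1; 0.588). For cell structure they were 2 and 0 of 24 for the cell cycle (2 and 0; 0.237), 0 and 2 of 29 for extracellular matrix (0 and 2; 0.237), 1 and 1 of 19 for junctions (1 and 1; 0.796), 2 and 0 of 15 for endothelial (2 and 0; 0.63), 0 and 2 of 11 for smooth muscle (0 and 3; 0.146) and 3 and 5 of 23 for histone genes (4 and 6; 0.588). The neutrophil list again had too few members (2 genes, median -0.11). Over the 561 list members tested, 52 were called, 21 higher and 31 lower. Median, mean and test differed in sign for 8 uncalled lists: steroidogenesis, growth hormone and IGF, innate sensing, oxidative stress, junctions, endothelial, histones and Leydig. With the preset correlation macrophage genes were called without genes in the clustered bins (0.0447) and with the GC and length correction (0.0372). Meiotic spermatocyte genes were called with that correction (0.0343). No testis list had an adjusted p below 0.755 with an estimated correlation and all libraries. Without single libraries, cholesterol biosynthesis was called without CV1 (0.0169) or CV2 (0.00558), macrophage (0.0414), extracellular matrix (0.000528) and smooth muscle genes (0.0393) without CV2, and MHC class II without GF3 (0.00468), so that without CV2 6 lists were called in place of 2. These calls too rest on the preset correlation. With an estimated correlation the adjusted p was 0.804 for cholesterol biosynthesis, 0.904 for extracellular matrix and 0.755 for macrophage, smooth muscle and MHC class II genes.

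The GF minus CV difference was not the same in both tissues for 29 genes by the interaction test, 11 of them in the clustered bins, among these Ryr2, Akr1c21, Zscan12, Hist1h2bp, Hist1h2ae and Pom121l2. Outside the bins, Mapkapk2, Swt1 and Dars lay on chromosome 1, Nnt on chromosome 13 and Hes1 on chromosome 16. Chromosomes 1 and 13 held excess testis calls (12.9% and 15.5% of their tested genes, against 7.88% elsewhere for each). A strain background was not told apart from the microbiota here either. Mapkapk2, a stress-activated kinase, went from 20.2 to 43.2 CPM in the testis and from 110 to 114 in the ovary, a testis minus ovary difference of 1.03 in log2 (SE 0.0783, edgeR adjusted p = 5.38e-06). Hes1, a transcriptional repressor of Notch signalling, went from 6.43 to 15.8 CPM in the testis and from 32.7 to 28.9 in the ovary (1.46, SE 0.157, 0.000199). Ryr2 went from 1.19 to 6.05 and from 69.5 to 99.9 CPM (1.79, 0.000162), and Akr1c21 (8.36, 0.00168) from 20 to 196 counts in the testis against 12 and 0 in the ovary, where its fitted change depends on a prior count. Nnt, called in both tissues and chosen here after its value was seen, rose more in the ovary (-0.73, SE 0.106, adjusted p = 0.00528). Negative differences were also found for Swt1 (43.9 to 45.6 CPM in the ovary, 83.8 to 56.9 in the testis; -0.63, 0.000309), the aspartyl-tRNA synthetase Dars (129 to 112 and 136 to 83.3 CPM; -0.52, 0.00384), the zinc finger gene Zscan12 (19.5 to 18.5 and 75 to 41.7 CPM; -0.79, 0.00482), Hist1h2bp (2.38 to 10.2 and 41.3 to 40.5 CPM; -2.15, 0.000162) and Pom121l2 (1 to 43 counts in the ovary and 172 to 181 CPM in the testis; -4.48, 0.000162). Hist1h2ae differed by 2.69 (adjusted p = 0.0034). Of 21977 genes tested, 29 were called, 16 with a positive and 13 with a negative difference, and 1524 had an unadjusted p under 0.05. The positive share was 55.2%, and 68% of 25 calls with upper-quartile scaling. The count fell below 20 without any 1 of the testis libraries: 19 without CV1, 18 without CV2, 14 without CV3, 18 without CV4, 17 without GF1, 14 without GF2 and 13 without GF3. It was 127 with DESeq2, 85 with limma and quality weights, 16 on the partnered libraries and 9 without genes in the clustered bins.

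Genes called in both tissues by edgeR all moved in the same direction. Of the 31 ovary calls that were tested in both tissues 27 were also called in the testis, 18 higher in both (0.75 for independent lists, Fisher's exact test, p = 2.99e-24) and 9 lower in both (0.368, p = 2.56e-12), with 0 of opposite direction. The 18 include Prl2c5 with the 7SK and SNORA73 copies that share its counts, and Dynlt1b with AC183097.2, so that these entries are not independent. With 1 entry for each of these sets, 15 were higher in both (0.635 for independent lists, Fisher's exact test, p = 4.07e-20). Besides Prl2c5, SLC25A37 and 5 histone genes (Hist1h2ao, Hist1h4i, Hist1h4m, Hist1h2bm, Hist1h2bn), they held ERDR1 (log2 -1.47 in the ovary, -1.32 in the testis), Dynlt1b (1.09, 0.92) and Ero1lb (-0.89, -1.08). Also among them were Hist1h4n (1.26, 0.89), Efcab7 (0.95, 0.79), Gpr137b (1.08, 0.76), Wdfy1 (1.18, 0.75) and Nnt (1.09, 0.38), chosen after their values were seen. In the testis ERDR1 (adjusted p = 0.0192) was not called without CV1 (0.0602), CV3 (0.0682) or GF1 (0.0846; over all settings 4.67e-20 to 0.0846). Of the 27, 17 lay on chromosome 13, 16 in the clustered bins, 3 had no position and 12 were predicted or unnamed. The 4 ovary calls not called in the testis were Hist1h2bp, Cntnap5a, Ggps1 and the galectin Lgals8, chosen after their values were seen, and Igha was not tested there, with 4 and 0 counts. DESeq2 gave 41 shared genes, 23 higher and 17 lower in both, and 1 of opposite direction, Rabgap1l (-0.23 in the ovary, adjusted p = 0.00413, and 0.12 in the testis, 0.0346), chosen after its values were seen. By edgeR 9 were left without genes in the clustered bins.

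**Figure D4:**
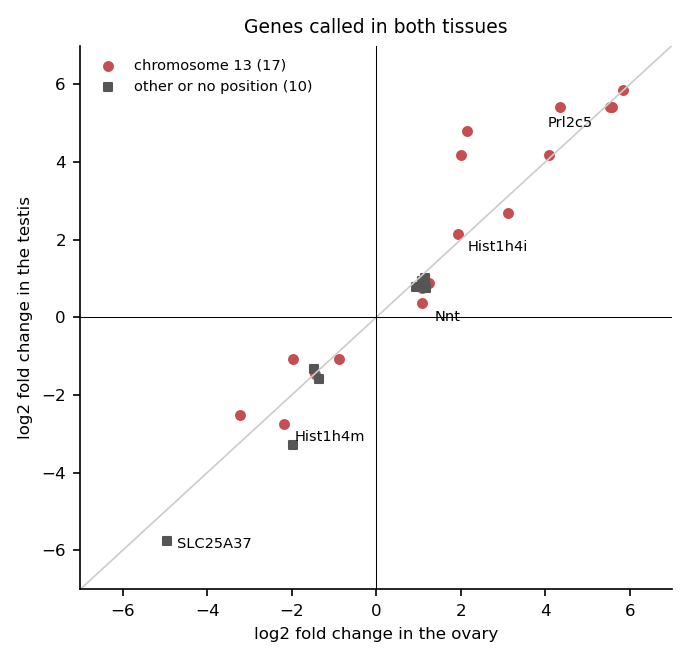
Log2 fold change (GF over CV) in the ovary against that in the testis for the 27 genes called in both, 1 point per gene, red for the 17 on chromosome 13 and grey squares for the 10 elsewhere or without a position, with the line of equal change. Every point lies in the quadrant of equal sign.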

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

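The 5 Mb bins, the tests of strain background and of shared reads, and the comparisons of spermatogonia with Sertoli cell genes were chosen after the results they bear on were seen. The GC and length correction was added after the data were seen, with its test set before its result, as was the corpus luteum covariate for the lists, and the other splits were planned.

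Called genes clustered in 8 bins of 5 Mb on chromosomes 1, 5, 12 and 13 that held 19 of the 32 ovary and 111 of the 1638 testis calls, while shuffled gene positions gave a clustered bin in 2 (ovary) and 4 (testis) of 200 shuffles. GC content and gene length are argued against as the cause, since 8 of the 8 testis bins still held clustered calls after the correction. Reads shared between near-identical copies are argued against as the whole cause: outside multi-copy families, a set widened once after a first run, 25.5% of ovary genes in the testis bins had an unadjusted p under 0.05 against 6.58% elsewhere (Fisher's exact test, p = 1.1e-12). A strain background that differs between the CV and GF colonies may account for the bins, since 29.9% of ovary genes in bins chosen from the testis calls alone had an unadjusted p under 0.05 against 6.21% elsewhere, and part of Nnt, which lies outside the bins, is deleted in the C57BL/6J substrain. Direction was shared only in part. Of testis calls in these bins 66 of 86 had the same sign in the ovary (76.7%, against 58.4% outside). For protein-coding genes outside multi-copy families it was 31 of 46 (67.4%, against 57.7%). The labels give the same strain, C57BL/6j, for all libraries, and Nnt RNA was lower in CV than in GF libraries of both tissues. The microbiota itself stays open for Nnt and the genes of the bins and was not tested against the colony, whose origin the labels do not give.

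Both spermatid lists were called lower in the GF testis with camera's preset correlation and not with an estimated one (adjusted p = 0.755 for both) or by fry (0.248 and 0.382). GC content and length are argued against for the preset calls, since both lists stayed under the threshold after the correction (larger adjusted p = 9.56e-05). A lower share of spermatids alone would lower most spermatid genes, and 33 of 37 were negative (89.2%), and it would raise the other cell types alike, while spermatogonia genes (14 of 18 positive) stood apart from Sertoli genes (6 of 22 positive). Over libraries the list means of these 2 parted by 0.18 in log2, which 2 of the 35 splits reached (exact permutation test, two-sided, p = 0.0571, adjusted 0.129 over 3 such pairs; smallest possible 0.0286), so a lower share of spermatids could account for the lists and stays open. Chance was not excluded, as 5 of the 35 splits of the testis libraries lowered both lists (highest other split 2 lists), and an effect of the microbiota stays open.

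Of 33 lists 11 were called in the ovary with camera's preset correlation, and 0 with an estimated correlation or by fry. Of the preset calls 8 of the 11 stayed under the threshold with the corpus luteum score as a covariate for cycle stage. The oviduct (0.0611), macrophage (0.0797) and clock (0.205) lists did not, and granulosa genes were newly called (0.00246). This cannot decide whether corpus luteum content is the cause, since other splits called a median of 9 lists with the same preset test. Chance was not excluded, since 41 of 100 splits of the ovary libraries gave as many lists (highest other 20, median 9), so the list calls of the ovary could arise from differences between single ovaries, and an effect of the microbiota stays open.

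For the number of genes called, chance was excluded by the other splits in the testis, and in the ovary where splits were not held to the pairs. The real split gave 32 genes in the ovary, reached by 1 of 100 splits drawn from 126 (highest other 1, also among the 12 of the drawn splits that part all 4 pairs). The 12 drawn are too few for a share under 0.05, so with the pairs kept chance was not excluded. In the testis the real 1638 was reached by 1 of 35 splits, and the highest other, 667, came from a split that set the 3 GF libraries with 1 CV library against the other CV libraries, the next being 7. The 27 genes shared by both tissues were reached by 1 of 100 splits (highest other 0). Since no other ovary split drawn called more than 1 gene, this outcome was set by the ovary labels and does not test the sharing. For the interaction chance was not excluded. The 29 genes were reached by 4 of 100 splits drawn from 4410 (highest other 49), but most splits also undo the testis labels, and 83 of the 93 that do called 0 genes. The 6 splits drawn with the real testis labels and other ovary labels called 17 to 49.

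Single libraries stood far from the rest of their group in 9 of 162 sets of values (5.56%, where chance gives about 5%). Each set held a depth measure, a gene that checks the labels or a named gene in 1 group. Groups of fewer than 4 libraries could not be tested, so the 3 GF testis libraries were not checked. CV2 of the ovary was low in both oocyte genes, Gdf9 (30.5 CPM against 57.4 to 61.7) and Zp3 (18.2 against 26.8 to 27.8), and CV4 high in Hist1h2bm (26.8 against 22.1 to 22.6). GF4 of the ovary was high in Insl3 (13.3 CPM against 4.26 to 6.68). In the testis CV1 had 5.1 CPM of Xist against 0.368 to 0.531, and CV3 4.08 CPM of Nmur1 against 3.29 to 3.35 and 0.891 CPM of Ryr2 against 1.27 to 1.34. CV4 of the testis was low in Apoe (60.3 CPM against 65.9 to 66.4) and Catsper4 (94.7 against 101 to 102).

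By the test of the difference itself, GF minus CV differences were not the same in both tissues for 29 genes, 11 of them in the clustered bins. Mapkapk2, Swt1 and Dars lay outside the bins on chromosome 1, which held excess testis calls, so a strain background stays open for them. Testis minus ovary log2 differences were 1.03 for Mapkapk2, 1.46 for Hes1, 1.79 for Ryr2, 2.69 for Hist1h2ae and 8.36 for Akr1c21. They were -0.52 for Dars, -0.63 for Swt1, -0.73 for Nnt, -0.79 for Zscan12, -2.15 for Hist1h2bp and -4.48 for Pom121l2.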

How the results depend on the processing

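Fits without genes in the clustered bins, with the GC and length correction, with both that correction and the block, on the partnered libraries, with the block in the ovary alone for genes shared by both tissues and, for lists, with the corpus luteum covariate were chosen after the data were seen. The cause of the changes below was not tested, except that fewer genes or libraries enter where genes or libraries are left out.

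In the ovary, 32 genes became 95 with DESeq2, 91 with the replicate block, 90 with the block and the correction, 93 in the joint fit and 10 without the bins. The other settings gave 29 to 43, and 25 to 33 without 1 library. In the testis, 1638 genes became 122 in the joint fit, whose spread is shared with the more variable ovary, and 996 to 2084 without 1 library, with 1247 to 2084 in the other settings. For the interaction, 29 genes became 127 with DESeq2, 85 with limma and quality weights, 9 without the bins, 16 on the partnered libraries and 13 to 37 without 1 library. The 27 genes shared by both tissues became 41 with DESeq2, 9 without the bins and 22 to 28 without 1 library. The 11 ovary lists became 0 with an estimated correlation, 0 with fry and 7 to 11 without 1 library, and the 2 testis lists 0, 0 and 2 to 6, and 4 with the GC and length correction (macrophage, adjusted p = 0.0372, and spermatocyte, 0.0343, added).

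With the replicate block, which also left out GF5, the ovary call of the clock list ended and 5 lists were added. No other call of a named ovary gene or list changed. Without GF5 and with no block the clock call also ended (camera adjusted p = 0.13). Steroidogenesis (0.0499) and extracellular matrix (0.00234) were then called too, so these changes cannot be credited to the block alone. With the block and the correction together Hist1h2bn was no longer called (adjusted p = 0.0589, range 9.04e-10 to 0.106). In the testis, libraries of the same number did not deviate together (correlation -0.0427 to 0.0142 over 3 pairs, 0 pairs best matched), and the block gave 1692 genes, 1383 of them shared with the 1638, with Star (0.0232; over all settings 0.0232 to 1) and Hsd3b6 (0.00759; 0.00759 to 1) added. Among the genes reported here, the block in the testis, which also left out CV4, ended the calls of Fdps (0.0944), Lyz2 (0.107), Il1b (0.0846), Mki67 (0.0614), Acta2 (0.122) and Spo11 (0.0678). Without CV4 and with no block those of Fdps (0.0775), Lyz2 (0.0764), Il1b (0.0555) and Acta2 (0.0894) ended as well. The block gave 28 interaction genes, 17 of them shared, and 35 genes in both tissues, 38 with the block in the ovary alone.

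Over single named genes and all alternatives, 743 ovary values stayed on their side of the threshold and 27 lost the call, and 1407 testis values stayed, 144 lost the call and 5 gained it. The 11 interaction genes stayed called in all 291 fits. Of list values 510 stayed on their side, 56 lost and 27 gained a call in the ovary, and 447, 4 and 9 in the testis. No called value changed sign, and 47 of 2617 values of genes flipped sign where the gene was not called. In the ovary 4% of the smallest simulated changes were called, so small changes could be missed there. Depth and spread were not told apart as limits.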

Other observations

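The genes and counts here were chosen after their values were seen. Outside the clustered bins, the GF testis had more RNA of Fcgr3, an Fc receptor for immunoglobulin G (15.4 ± 0.586 to 40.9 ± 0.685 CPM, SD, n = 4 and 3; log2 1.41, edgeR adjusted p = 5.38e-21), of Gsdmd, the pore-forming protein of pyroptosis (4.56 to 10.6 CPM, 1.21, 1.05e-10), and of the endosomal GTPase gene Rab4a (3.27 to 7.61 CPM, 1.22, 4.72e-10). Scly, which recovers selenium from selenocysteine, rose from 13.6 to 31.7 CPM (1.22, 0.000438) and Kif1a, a kinesin motor, from 22.8 to 41 CPM (0.85, 4.05e-14), while Tbc1d7, a subunit of the tuberous sclerosis complex, fell from 16.2 to 8.26 CPM (-0.97, 3.48e-12). Fcgr3, Scly and Kif1a lie on chromosome 1 and Tbc1d7 on chromosome 13, while Gsdmd lies on chromosome 15 and Rab4a on chromosome 8. Chromosomes 1 and 13 held excess testis calls (12.9% and 15.5% of their tested genes, against 7.88% elsewhere for each). Scly, at 91298338, lies close to a clustered bin of chromosome 1 that ends at 90000000. In the ovary Fcgr3 stood at -0.10, Gsdmd at 0.08, Rab4a at 0.17, Scly at -0.10, Kif1a at 0.52 and Tbc1d7 at -0.09, none of these 6 called by edgeR there. The interaction test called Fcgr3 (1.49, adjusted p = 0.0474), Gsdmd (1.11, 0.0395), Rab4a (1.03, 0.00533) and Scly (1.30, 0.0166).

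Antibody genes other than Igha had counts in GF ovaries. Ighm had 1046 counts over the 4 CV and 1168 over the 5 GF libraries and Ighg3 39 and 122, while Igkc had 401 and 199 and Igj (Jchain) 255 and 117. Among testis genes by annotated type, 8.91% of protein-coding, 7.3% of long non-coding and 4.87% of pseudogene entries were called.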
